A study of Homo sapiens with 4 samples.

How the data were processed

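RNA was profiled from AGS cells, a line derived from a human gastric adenocarcinoma, transduced with a vector (2 libraries) or with SLC7A9 (2 libraries). Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I, checked for integrity and made into Illumina libraries. The kit, whether poly(A) selection or ribosomal depletion was used, and whether libraries kept the strand are not given in the sources used here. The submitters' processing notes name fastp, HISAT and RSEM and the build GRCh38.p13, without versions or roles.

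The authors deposited 1 table with a value per gene and library. Its header names no unit, and the deposited values were read as FPKM, fragments scaled to the length of the transcript and to the mapped fragments of the library. That reading rests on the values: they are decimals, and the columns sum to between 450982 and 474627 although the abundant mitochondrially encoded and ribosomal protein genes are present, which TPM of these rows would not do. Low values showed no steps of whole reads, so the sequencing depth is unknown and no counting interval or detection limit is given. The table holds 23421 genes, 19974 with an Ensembl identifier (19922 of them protein coding) and 3447 newly assembled genes without a symbol. A listed 0 may be a failed estimate or an unexpressed gene. Genes such as ZNF32 stood at 0 in all 4 libraries, and which of these holds was not tested. Genes at 0 are therefore given per library and without a fold. The columns named for the vector matched the vector samples. The other 2 columns are numbered 1 and 2 but do not name SLC7A9, and were taken as the SLC7A9 samples of those numbers because no other columns or samples remained.

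From there, genes with at least 1 FPKM in at least 2 libraries were kept (11671 genes, 913 of them newly assembled), and log2(FPKM + 1) was compared between SLC7A9 and vector cells with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes in log2 are on the log2(FPKM + 1) scale, which understates the change of low genes. Fold values quoted as such are ratios of mean FPKM. With 2 libraries against 2, an exact permutation test of a single value has 3 splits and cannot go below p = 0.333. The p-values of single genes therefore come from limma, which borrows the spread across genes (2 residual and 5.10 prior degrees of freedom). The labels do not say whether the libraries of a group came from separate cultures. The p-values of single genes then measure only the spread between these samples, which may be technical.

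Before the data were examined, 29 gene lists with 1046 entries were fixed, covering amino acid transport and stress, redox, lipid, hypoxia, cell cycle, signalling, epithelial, ribosomal, mitochondrial and histone genes and markers of other cell types. Of the entries, 1040 matched a gene of the table by symbol or older symbol. Lists with at least 5 tested members (27 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. This test sets list members against the other genes, so its p does not measure the spread between libraries. Camera with an estimated correlation and fry were run beside it. The estimates ran from -0.18 (gastric and intestinal markers) to 0.54 (cytosolic ribosomal proteins), with 0.026 for hypoxia and 0.33 for cholesterol. That version also takes its p from the 2 residual degrees of freedom, so a lost call need not come from correlated genes. For the unfolded protein response the estimate was -0.032, below the preset, yet the unadjusted camera p went from 6.79e-04 to 0.0619. The genes named were also set by a rule fixed in advance. They are SLC7A9 and SLC3A1, the 8 largest increases and 8 largest decreases among called genes with a symbol, a mean of at least 1 FPKM in the higher group and no overlap between groups, and from each list up to 3 called members with the smallest adjusted p. One of the genes picked by this rule is left out of the text and is not reported here. Where other genes are named, this is said.

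Gene positions and overlaps of exons on the same strand were taken from GENCODE release 29 (GRCh38), in which all 19974 Ensembl identifiers were found, 19925 with the same symbol. Symbols are given as in the table. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The procedure was tested on simulated data with the means and spread of the 11671 genes, 200 of them changed per run, over 10 runs. It called 13.3% of genes changed 1.5-fold, 70.7% of those changed 2-fold and 99.1% of those changed 4-fold, and 5.42% of its calls were unchanged genes. These folds were set on the log2(FPKM + 1) scale, so for low genes they stand for larger ratios of FPKM. Errors were normal, with spreads drawn much as limma assumes and without effects shared by a library. The share of unchanged genes among the calls is therefore no independent check. Camera called 10 of 10 shifted lists and 0 of 100 unshifted ones, in data simulated without correlation between genes.

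The alternatives tried were quantile normalization, no filter, a stricter filter of 5 FPKM, a pseudocount of 0.1, the replicate number as a block, limma without the trend, and each library left out in turn, in which case a lone library is assumed to vary like the other group. Leaving out the trend changed only the tests of single genes, so for lists it repeats the main result. Chosen after seeing the data were scaling to the same sum, to the same sum of nuclear genes and by the median of ratios, annotated genes only, leaving out genes that overlap another on the same strand, and the transporter list without SLC7A9. Also outside the plan was the Fisher's exact test of the share of list members among called genes.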

Results

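The data set held 4 RNA-seq libraries of AGS gastric cancer cells, 2 from cells transduced with a vector and 2 from cells transduced with SLC7A9, and the comparison asked how SLC7A9 affects gene expression in these cells. Vector libraries summed to 474627 and 462493 FPKM and SLC7A9 libraries to 450982 and 459862 FPKM. At least 1 FPKM was reached by 11428 and 11497 genes in the vector libraries and by 11636 and 11497 genes in the SLC7A9 libraries. Across the 11671 tested genes, which are not independent replicates, Pearson's r of log2 values was 0.987 and 0.988 within the groups and 0.978 to 0.984 between libraries of different groups.

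SLC7A9 encodes the light subunit of the b0,+ transporter, which carries cystine and dibasic amino acids and pairs with the heavy subunit SLC3A1. SLC7A9 (ENSG00000021488, chromosome 19, 32830509 to 32869766, minus strand, GRCh38) was listed at 0 in both vector libraries and at 43.6 and 41.9 FPKM in the SLC7A9 libraries. The difference was 5.45 on the log2(FPKM + 1) scale (SE 0.126, n = 2 per group, limma adjusted p = 8.53e-06). The table gives 1 value per gene and does not separate the introduced copy from the gene of the cells. SLC3A1 (chromosome 2, 44275458 to 44321494, plus strand) stood at 0.024 and 0 FPKM in vector cells and at 0.011 and 0.035 FPKM in SLC7A9 cells, too low to be tested.

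Besides SLC7A9, called genes that rose in SLC7A9 cells included EGLN3, ADM and PLIN2, and called genes that fell included SAA1, CHAC1 and TXNIP. Among called genes with a symbol that overlap no other gene on the same strand, these had the largest changes on the log2(FPKM + 1) scale. EGLN3 went from 3.85 and 4.06 to 14.1 and 16.2 FPKM (n = 2 per group), and SAA1 from 18.7 ± 0.623 to 5.02 ± 1.92 FPKM (SD, n = 2 per group). In all, 56 of 11671 genes passed the threshold, 36 higher and 20 lower in SLC7A9 cells, 42 of them with an absolute log2 fold change of at least 1. At an unadjusted p under 0.05 there were 1681 genes, and all 56 called genes had both libraries of one group above both of the other. Of all tested genes, 30.2% had both SLC7A9 libraries above both vector libraries and 18.1% had them below, where chance gives 16.7% each way. These shares use the deposited values without further scaling, in which the median log2 fold change of all tested genes was 0.044. They were not recomputed after scaling, so they cannot separate a shift of all values from changes of single genes. With median-of-ratios scaling that median was -8.0e-04, and the calls split into 33 higher and 32 lower. The number of calls was 29 without vector replicate 1, 13 without vector replicate 2, 273 without SLC7A9 replicate 1 (99 higher and 174 lower) and 119 without SLC7A9 replicate 2, and with no filter on low values limma called 1 gene, SLC7A9. The 24 genes called and named by the rule kept their direction with any 1 library left out. That was fixed in advance, because both libraries of one group lay above both of the other.

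Of the 35 tested genes of the hypoxia and glycolysis list, 32 had a positive and 3 a negative log2 fold change in SLC7A9 cells. ADM, which encodes the vasodilator peptide adrenomedullin, rose from 8.42 ± 0.478 to 28.4 ± 0.357 FPKM (3.38-fold). EGLN3, a prolyl hydroxylase that marks HIF proteins for degradation, rose 3.83-fold, PFKFB4, an enzyme that sets the level of fructose 2,6-bisphosphate, rose 3.34-fold, and NDRG1, a stress-responsive gene, rose 2.46-fold (limma adjusted p = 0.00472 for each of the 3). Of the 35 list members tested, 11 were called higher and 0 lower over all genes, and 22 higher and 1 lower when adjusted over the list alone. Both SLC7A9 libraries lay above both vector libraries for 26 of the 35 members and below them for 2, against 30.2% and 18.1% of all tested genes. The 11 also include the glucose transporters SLC2A1 and SLC2A3 and the glycolytic enzymes HK2 and ENO2, named after their values were seen. SLC2A3 stood at 50.4 and 43.7 FPKM in vector cells and at 102 and 111 FPKM in SLC7A9 cells. The list's median log2 fold change was 0.55 (camera adjusted p = 2.50e-15). This call was lost in camera with an estimated correlation, which also rests on the 2 residual degrees of freedom (adjusted p = 0.545). Fry gave an adjusted p of 0.0507. List members made up 11 of the 36 genes called higher, against 35 of the 11671 genes tested (two-sided Fisher's exact test across genes, p = 1.75e-20). This test was not planned and was run for this list and the cholesterol list only. It treats genes as independent, so its p does not measure the spread between libraries. Without vector replicate 2, NDRG1 did not pass in limma, with a log2 fold change of 1.26 against 1.28 with all libraries. Of the list's called members, only EGLN3, ADM, PFKFB4 and NDRG1 were followed when single libraries were left out. Whether the other called members pass without a single library is not given.

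**Figure D1:**
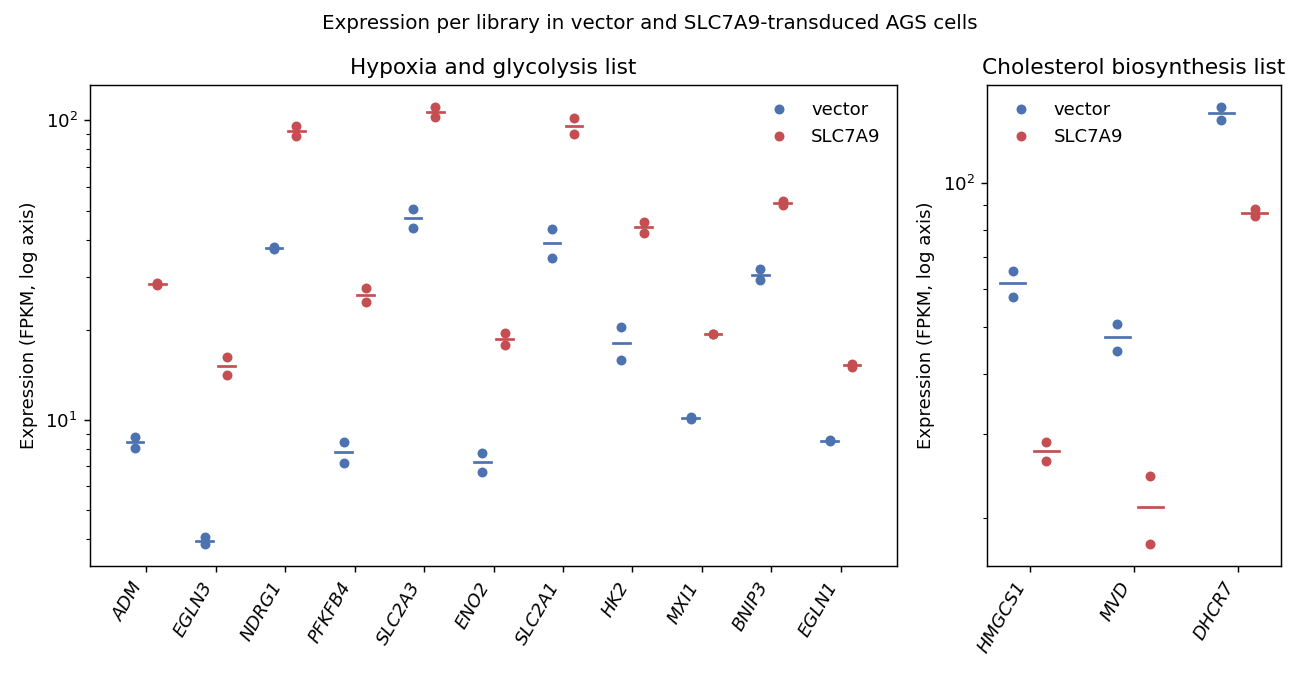
FPKM (log axis) of the 11 called genes of the hypoxia and glycolysis list (left) and the 3 called genes of the cholesterol biosynthesis list (right), with a limma adjusted p under 0.05. Each point is a library, each bar the mean of the 2 libraries of a group, blue for vector and red for SLC7A9, and the SLC7A9 libraries lie above the vector libraries in all 11 genes on the left and below them in all 3 on the right.

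All 24 tested genes of the cholesterol biosynthesis list had a negative log2 fold change. HMGCS1, which makes HMG-CoA in the mevalonate pathway, fell from 61.8 ± 5.41 to 27.6 ± 1.76 FPKM (log2 fold change -1.14, SE 0.112, n = 2 per group, limma adjusted p = 0.0113). MVD, the mevalonate diphosphate decarboxylase, was 2.27 times higher in vector cells (47.7 ± 4.42 FPKM there, adjusted p = 0.0419), and DHCR7, which catalyses a last step to cholesterol, fell from 140.1 ± 6.06 to 86.8 ± 2.19 FPKM (adjusted p = 0.0434). Of 24 members tested, these 3 were called lower over all genes and 0 higher, and 20 were lower when adjusted over the list alone. Both SLC7A9 libraries lay below both vector libraries for 21 of the 24, against 18.1% of all tested genes. The median log2 fold change was -0.51 (camera adjusted p = 2.65e-20, but adjusted p = 0.558 with an estimated correlation, and 0.0824 with fry). Without vector replicate 2 the limma adjusted p was 0.0856 for HMGCS1, 0.170 for MVD and 0.218 for DHCR7. Without vector replicate 1 it was 0.219 for MVD and 0.237 for DHCR7.

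PLIN2, a coat protein of lipid droplets, was the only called member among the 20 tested genes of the fatty acid synthesis list. It rose from 114 ± 9.08 to 348 ± 43.3 FPKM (3.05-fold, limma adjusted p = 0.00472, and 0.0520 without vector replicate 2). Adjusted over the list alone, 1 gene was higher and 4 were lower, and the list did not pass (median -0.068, camera adjusted p = 0.116), except without vector replicate 1 (adjusted p = 0.0150, range over the 15 alternatives 0.0150 to 0.611).

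Target genes of the amino acid response and ATF4 fell as a list. CHAC1, an enzyme that degrades glutathione, fell from 16.3 ± 0.482 to 5.03 ± 0.436 FPKM (3.24 times higher in vector cells, limma adjusted p = 0.00511, and 0.0530 without vector replicate 2). TRIB3, a pseudokinase induced by ATF4, fell from 51.8 ± 1.55 FPKM and was 1.73 times higher in vector cells (limma adjusted p = 0.0301, but 0.152 without vector replicate 1 and 0.223 without vector replicate 2). These were the 2 called genes among 43 tested, and adjusted over the list alone 7 were lower and 2 higher. Both SLC7A9 libraries lay below both vector libraries for 21 of the 43 and above them for 4, against 18.1% and 30.2% of all tested genes. The median was -0.15 (camera adjusted p = 3.58e-05, adjusted p = 0.558 with an estimated correlation, and 0.210 with fry).

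Among amino acid transporters, SLC7A9 was the only one of 18 tested genes to pass over all genes, and adjusted over the list alone 2 were higher and 3 lower. SLC3A2, the heavy subunit of other cystine and neutral amino acid transporters, stood at 161 and 156 FPKM in vector cells and at 123 and 117 FPKM in SLC7A9 cells (limma adjusted p = 0.183). SLC7A11, the cystine and glutamate exchanger, stood at 15.5 and 25.1 FPKM against 13.7 and 12.2 FPKM (adjusted p = 0.309). Both were named after their values were seen. The list's median was -0.23 and its mean, which SLC7A9 itself raises, was 0.15. Camera gave an adjusted p of 0.0846 toward lower values and fry one of 0.0232 toward higher values. Without SLC7A9, an alternative chosen after seeing the data, the other 17 genes had a median of -0.25 (camera adjusted p = 0.00567, adjusted p = 0.498 with an estimated correlation, and 0.0507 with fry, all toward lower values).

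Glutathione and cysteine genes passed camera toward lower values, with CHAC1 the only called gene among 26 tested and 3 lower when adjusted over the list alone. The median of all tested genes was 0.044, and 0.079 with every library scaled to the same sum. That of the glutathione and cysteine genes was -0.038 (camera adjusted p = 0.0315, adjusted p = 0.658 with an estimated correlation, and 0.571 with fry). This call ended with quantile normalization (adjusted p = 0.115), without vector replicate 2 (adjusted p = 0.207) and without SLC7A9 replicate 1 (adjusted p = 0.830), and with every library scaled to the same sum the median was above 0 (0.0020, adjusted p = 0.0569). Over the 15 alternatives the adjusted p ran from 1.94e-05 to 0.830. Ferroptosis regulators (25 tested, CHAC1 called, 2 lower adjusted over the list alone, median 0.0083, camera adjusted p = 0.480) and NRF2 targets (30 tested, 0 called over all genes and 0 adjusted over the list alone, median 0.015, camera adjusted p = 0.922) did not pass.

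Genes of the unfolded protein response were higher as a list, with a median of 0.19 over 28 genes (camera adjusted p = 0.00366). The list did not pass with an estimated correlation (adjusted p = 0.558) or with fry (adjusted p = 0.0795). No member was called over all genes or when adjusted over the list alone, while 17 lay higher and 1 lower in both SLC7A9 libraries than in both vector libraries, against 30.2% and 18.1% of all tested genes. The chaperone HSPA5, named after its values were seen, stood at 187 and 177 FPKM in vector cells and at 237 and 239 FPKM in SLC7A9 cells (limma adjusted p = 0.197). Without vector replicate 2 the list had a camera adjusted p of 0.0733, the highest over the 15 alternatives (lowest 5.39e-04).

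The 13 mitochondrially encoded transcripts fell as a list, with a median of -0.23 (camera adjusted p = 1.46e-04). The list had 0 called genes over all genes or adjusted over the list alone. It did not pass with an estimated correlation (adjusted p = 0.558) or with fry (adjusted p = 0.210). Both SLC7A9 libraries lay below both vector libraries for 11 of them, against 18.1% of all tested genes. These transcripts took 18.4% and 17.4% of all FPKM in vector cells and 16.6% and 14.98% in SLC7A9 cells. With quantile normalization the list's median was -0.043 (adjusted p = 0.238, the highest over the 15 alternatives, the lowest being 2.16e-05).

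Nuclear oxidative phosphorylation genes (73 tested, median -0.013) and cytosolic ribosomal protein genes (78 tested, median -0.052) passed camera toward lower values with an adjusted p of 0.0291 each, and 0 members were called over all genes or adjusted over the list alone. The median of all tested genes was 0.044, and 0.079 with every library scaled to the same sum. The calls of the 2 lists were lost with an estimated correlation (adjusted p = 0.658 for the first list and 0.792 for the second). Neither list passed fry (adjusted p = 0.681 and 0.865). Without SLC7A9 replicate 1 the medians were 0.028 (adjusted p = 0.722) and 0.094 (adjusted p = 0.522). Without vector replicate 2 they were -0.0033 (adjusted p = 0.173) and 0.039 (adjusted p = 0.722), and with every library scaled to the same sum the oxidative phosphorylation median was above 0 (0.027, adjusted p = 0.0597) and the ribosomal one was -0.012 (adjusted p = 0.0597). With quantile normalization the adjusted p was 0.132 and 0.881, without overlapping genes it was 0.122 for the first list, and with no filter 0.0571 for the second. Over the 15 alternatives the adjusted p ran from 3.42e-05 to 0.722 for the first list and from 2.38e-10 to 0.881 for the second.

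Secreted and signalling genes were among those that fell. The acute-phase genes SAA1 (3.72 times higher in vector cells, limma adjusted p = 0.0231) and SERPINA3 (4.48 times, adjusted p = 0.0135) were lower in SLC7A9 cells, as was TXNIP, a glucose-responsive inhibitor of thioredoxin (50.9 ± 8.55 to 21.1 ± 2.68 FPKM, adjusted p = 0.0231). DUSP6, a phosphatase of ERK, fell from 8.92 ± 1.20 to 3.92 ± 0.0742 FPKM (adjusted p = 0.0412), and CTGF, a matrix protein and YAP target, from 66.2 ± 2.57 to 40.8 ± 1.73 FPKM (adjusted p = 0.0482). Without vector replicate 2 none of these 5 passed (limma adjusted p = 0.170 for SAA1, 0.115 for SERPINA3, 0.136 for TXNIP and DUSP6 and 0.223 for CTGF). Without vector replicate 1, SAA1 (adjusted p = 0.124), DUSP6 (0.220) and CTGF (0.237) did not pass in limma.

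The lists that hold these genes did not pass camera with all 4 libraries. NF-kB and cytokine targets had a median of -0.012 (adjusted p = 0.0817, but 0.00872 without SLC7A9 replicate 2, range over the 15 alternatives 0.00872 to 0.352), MAPK and immediate early genes -0.030 (0.180), mesenchymal and matrix genes 0.12 (0.180) and YAP targets 0.093 (0.934). Over all genes, SAA1 was the only call among 22 NF-kB genes, DUSP6 among 27 MAPK genes and CTGF among 27 YAP targets. Of 41 mesenchymal genes, 1 was called higher and 1 lower, the latter being CTGF. Adjusted over the list alone, 0 NF-kB genes were higher and 2 lower, 5 MAPK genes higher and 5 lower, 4 mesenchymal genes higher and 3 lower, and 1 YAP target higher and 2 lower.

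Cell cycle genes did not pass, with a median of 0.039 for 49 G1/S genes (camera adjusted p = 0.922) and 0.059 for 47 G2/M genes (adjusted p = 0.480). The same held for p53 targets (median 0.072, adjusted p = 0.641), apoptosis regulators (-0.012, 0.641), interferon response genes (-0.020, 0.558), Wnt and stem cell targets (0.067, 0.180), epithelial adhesion genes (-0.12, 0.0846, but 0.0307 without vector replicate 1, range over the 15 alternatives 0.0307 to 0.414), gastric and intestinal markers (-0.36 over 5 genes, 0.0846), drug transport and metabolism genes (-0.069, 0.729) and replication-dependent histones (-0.0065, 0.221). These 10 lists held 0 called genes over all genes. Adjusted over the list alone, 1 G1/S gene, 1 Wnt gene and 1 epithelial gene were higher and 1 p53 target and 1 epithelial gene lower. Camera's direction rests on the members' moderated statistics relative to the other genes, not on the median. It was lower for p53 targets, ferroptosis regulators, NRF2 targets and fibroblast and endothelial markers although their medians were above 0. For p53 targets and fibroblast and endothelial markers the median (0.072 and 0.16) also lay above that of all tested genes (0.044). Their mean log2 fold changes were -0.023 and 0.020.

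**Figure D2:**
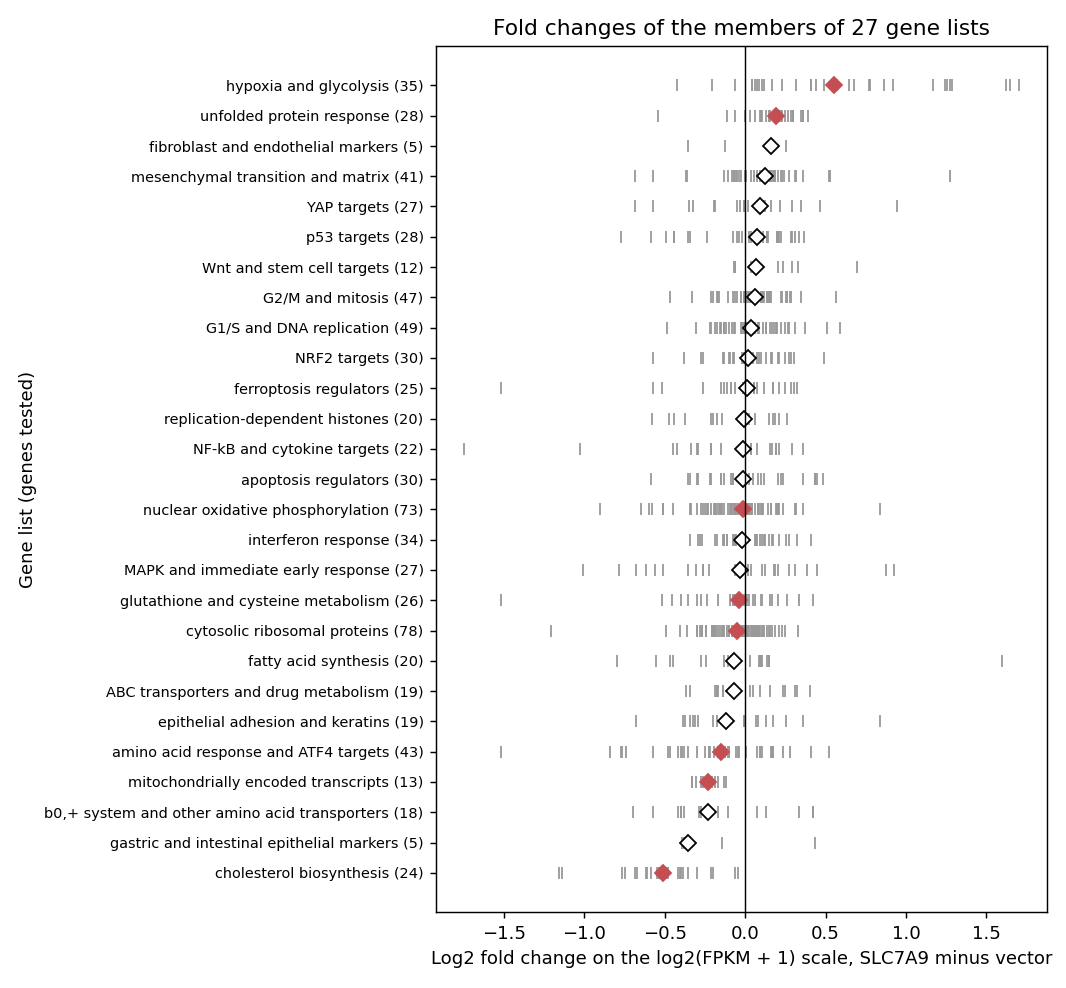
Log2 fold changes (SLC7A9 minus vector, log2(FPKM + 1) scale, horizontal axis) of the tested members of 27 gene lists, with the number of tested genes in brackets. Grey ticks are genes, without SLC7A9 itself at 5.45, diamonds are list medians with SLC7A9 included, and filled diamonds mark a camera adjusted p under 0.05. The hypoxia and glycolysis list has the highest median (0.55) and the cholesterol biosynthesis list the lowest (-0.51).

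Markers of other cell types were low. Among 15 fibroblast and endothelial genes, 5 were tested, none above 9.89 FPKM in any library, with a median of 0.16 (camera adjusted p = 0.922). Of 15 immune genes, CD68, which many cell types express, was the only one tested, at 11.5 and 14.9 FPKM in vector cells and 18.5 and 19.0 FPKM in SLC7A9 cells (limma adjusted p = 0.252). Of 11 markers of packaging cells, NTS stood at 3.68 and 4.26 FPKM against 6.61 and 6.95 FPKM (adjusted p = 0.134), and NEFH between 4.24 and 4.88 FPKM in the 4 libraries. CD68 and NTS were each higher when adjusted over the list alone. With 1 tested gene in the immune list and 2 in the packaging list, that adjusts little or nothing. At an unadjusted limma p under 0.05, 1681 of all 11671 tested genes passed. CD68, NTS and NEFH were named after their values were seen.

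Several of the largest differences belonged to genes that share exons with another gene on the same strand, and their values are uncertain for that reason. Of 52 annotated called genes, 12 did so. HINT2 (chromosome 9, 35812960 to 35815354, minus strand) was listed at 6.38 and 6.12 FPKM in vector cells and at 0 in both SLC7A9 libraries (limma adjusted p = 0.00203), while AL133410.3, a gene model that shares exons with HINT2, was listed at 0 in vector cells and at 2.07 and 1.84 FPKM in SLC7A9 cells (adjusted p = 0.0209). AL133410.3 was named after its values were seen. PMF1-BGLAP, which joins PMF1 and BGLAP, was 11.2 ± 0.546 FPKM in vector cells and 1.86 ± 0.0372 FPKM in SLC7A9 cells (adjusted p = 0.00316). AC023055.1 was 0.066 and 0.081 FPKM against 5.24 and 4.48 FPKM (adjusted p = 0.00371), AC135050.2 was 0 against 3.46 and 2.64 FPKM (0.0108), and BCL2L2-PABPN1 was 0 against 1.83 and 2.29 FPKM (0.0209). AC005943.1 was 8.04 and 3.49 FPKM in vector cells and 0 in SLC7A9 cells (0.0209), and AC026464.4 was 1.70 and 2.72 FPKM against 0.040 and 0 (0.0321). PFKFB4 and SERPINA3 also share exons with another gene. In limma without vector replicate 1, AC135050.2 (adjusted p = 0.0521), BCL2L2-PABPN1 (0.124) and AC026464.4 (0.0932) did not pass, and without vector replicate 2 the values were 0.0716, 0.146 and 0.259.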

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

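The 3 scalings, annotated genes only, the filter on overlapping genes and the transporter list without SLC7A9 were chosen after seeing the data. The SLC7A9 difference kept its direction and limma call under all 15 alternatives (5.42 to 8.74, highest adjusted p 0.0112). The hypoxia (median 0.44 to 0.58), cholesterol (-0.59 to -0.37) and amino acid response lists (-0.22 to -0.093) kept their direction and camera call under the same alternatives. For lists, leaving out the trend repeats the main result, because it did not enter camera. The hypoxia, cholesterol and amino acid response lists each lost their call with an estimated correlation (adjusted p = 0.545, 0.558 and 0.558), where camera called 0 of the 27 lists. With its 2 residual degrees of freedom that version leaves little room for a call, so the loss does not show correlated genes. Fry called 1 of the 27 lists, that of the transporters, toward higher values and with SLC7A9 itself among its members. Camera did not call that list. Without SLC7A9, fry gave it an adjusted p of 0.0507 toward lower values. The count of 56 genes, 36 higher and 20 lower, became 1, 1 and 0 with no filter, for which the cause was not tested. Leaving out 1 library gave 13 to 273 calls, 10 to 99 higher and 3 to 174 lower, with fewer samples. Lower genes numbered 11 without the trend, cause not tested, and 31 without overlapping genes, where fewer genes were tested. They numbered 32 with median-of-ratios scaling, which divides vector libraries by 0.982 and 0.987 and SLC7A9 libraries by 1.03 and 1.01. That lowers SLC7A9 values relative to vector values, and the median log2 fold change of all tested genes went from 0.044 to -8.0e-04. With the replicate number as a block there were 429 calls, 202 higher and 227 lower, 56 of them the main ones, and of the 8 called lists the glutathione list lost its call under the block (adjusted p = 0.0611). Libraries with the same number deviated together only weakly (r = 0.130 across genes), and 2 pairs cannot show that numbers pair the samples. The 8 called lists became 4 with quantile normalization, 5 with scaling to the same sum, and 4 to 10 without single libraries, causes not tested. The median of ribosomal protein genes lay between -0.14 and 0.094 without single libraries, above 0 without vector replicate 2 (0.039, adjusted p = 0.722) and without SLC7A9 replicate 1 (0.094, adjusted p = 0.522), where camera's direction also turned, cause not tested (adjusted p up to 0.881 over the alternatives). Of the 24 named calls, 24 passed with each scaling and with quantile normalization. A pseudocount of 0.1 left 23 (without CTGF), leaving out the trend 17 and no filter 1. Their directions did not change with the scalings or quantile normalization, and in the other settings of this comparison they could not change. The edgeR test planned for counts, DESeq2 and limma-voom all need counts and were not run, and without depth the precision of low genes cannot be given.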

Other observations

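The genes in the next paragraph were chosen after their values were seen, and so were all tests below except that of switching within a group.

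MT2A and MT1E, metallothioneins that bind zinc and copper, fell in SLC7A9 cells. MT2A went from 1266 and 1592 FPKM in vector cells to 715.0 and 750.3 FPKM (limma adjusted p = 0.0482), and MT1E from 592 and 687 to 299.7 and 334 FPKM (adjusted p = 0.0231). The other 3 tested members, MT1X, MT1F and MT1G, did not pass (adjusted p = 0.257, 0.312 and 0.0654), and all 5 had both SLC7A9 libraries below both vector libraries, against 18.1% of all tested genes, also under each of the 3 other scalings. Outside the fixed lists, genes that rose included STC1, a secreted glycoprotein (17.1 and 20.5 to 51.0 and 48.3 FPKM, adjusted p = 0.00774), HILPDA, an inhibitor of lipolysis at lipid droplets (14.2 and 11.6 to 33.7 and 33.4 FPKM, 0.0108), and PPP1R3C, which promotes glycogen synthesis (5.73 and 6.13 to 14.6 and 15.7 FPKM, 0.0109). INSIG2, which retains the sterol sensor SCAP in the endoplasmic reticulum, rose from 9.55 and 8.70 to 20.3 and 19.2 FPKM (adjusted p = 0.0183), and RRAGA, a GTPase of amino acid sensing by mTORC1, from 51.4 ± 2.28 to 87.0 ± 5.07 FPKM (SD, n = 2 per group, limma adjusted p = 0.0357). GSTM3 differed by replicate number and not by group, at 3.84 and 13.95 FPKM in vector cells and 4.21 and 19.0 FPKM in SLC7A9 cells.

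The rise of the hypoxia and glycolysis list did not rest on 1 library, because the lowest of the 4 medians between an SLC7A9 and a vector library was 0.44 and the largest within a group was 0.094. A difference in oxygen supply or medium at harvest, shared by both libraries of a group, would leave the same within-group difference of 0.094 and cannot be told apart from an effect of SLC7A9. An effect of SLC7A9 itself stays open and untested.

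For the fall of the cholesterol list, medium or crowding at harvest, shared within a group (largest within-group median 0.15), cannot be told apart from an effect of SLC7A9, which stays untested.

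Genes listed at 0 in both libraries of one group and at 1 FPKM or more in both of the other numbered 6, SLC7A9 among them. The other 5 all share exons with another gene on the same strand, which makes 83.3% of the 6 against 11.5% of the other 11000 annotated genes that reach 1 FPKM (two-sided Fisher's exact test across genes, p = 1.12e-04). Between the 2 libraries of one group, 27 of 1275 such overlapping genes switched in the same way (2.12%) and 2 of 9731 other genes did (0.0206%, Fisher's exact test, p = 1.34e-23). Differences such as those of HINT2 and AL133410.3 may therefore come from how shared reads were assigned to overlapping gene models. A change in which transcripts the cells make stays open and untested.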
